A study of Mus musculus with 29 samples.

How the data were processed

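Lungs were taken from male lineage-tracing mice before intratracheal lipopolysaccharide (day 0) and 3 and 6 days after it, and sorted cells were profiled by droplet single-cell RNA sequencing. The mice carried a tamoxifen-inducible Cre recombinase under the Cx3cr1 promoter and a tdTomato reporter behind a floxed stop, so that cells expressing Cx3cr1 at the time of tamoxifen, and their progeny, became red fluorescent for good. Per the labels' protocols, tamoxifen was given at 0.25 mg per g of body weight to mice aged 10 to 12 weeks, and a dose of 20 µg of E. coli lipopolysaccharide followed 4 weeks later. An anti-CD45 antibody given into the airways marked airspace leukocytes before lavage, perfusion and enzymatic digestion of the lung. From each lung the sort took all CD45-positive cells, resident interstitial macrophages (CD64- and CD88-positive cells without the airway stain and with tdTomato) or recruited interstitial macrophages (the same gate without tdTomato). The target was 5000 cells for CD45-positive libraries and 3000 for macrophage libraries at 100000 reads per cell. There were 29 libraries in 9 groups, with n = 4 for both macrophage sorts at day 3 and n = 3 for every other group. Groups and replicate numbers came from the labels, which do not say which libraries come from the same mouse.

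For each library the authors deposited a sparse matrix of raw counts, which are unique molecular identifiers (UMIs) per gene and cell barcode, with the barcode and gene names. The submitters' processing notes name Cell Ranger 2.1.1 and the mm10 genome, whereas the matrix headers carry software version 3.0.2 in 8 libraries and 3.1.0 in 21. Version 3.0.2 was found in every replicate 1 library except the CD45-positive day 3 one, so it covers at most 1 library of a group and no comparison could be made within it. How reads shared by near-identical genes or by genes on opposite strands were counted is not given in the sources used here, so values of Ifit1, Ifit2, Gbp2, Gbp2b, Cxcl9, Cxcl10, the Ly6 and H2 families and the antisense gene AC163018.1 carry that uncertainty. The files held 31053 genes and 100405 barcodes. Total UMIs per library ran from 20016865 to 75250576, with 21834279 to 71260790 in CD45-positive, 20016865 to 57214995 in resident and 21874560 to 75250576 in recruited libraries. Median UMIs per barcode ran from 3827 to 16571.5.

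Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 87648 cells, between 77.3% and 94.1% of the barcodes of a library. Doublets were ranked by Scrublet score and the highest-scoring cells of each library were removed at a rate of 0.8% per 1000 cells, which marked 2286 cells, or 1.13% to 3.72% of a library. This rate replaced Scrublet's own thresholds after these had been seen to mark 0% to 2.31%. The CD45-positive and the macrophage libraries were clustered separately on 2000 variable genes, 40 principal components and 20 neighbours with Leiden resolution 1 and seed 0. A cluster was called "X-like" from cell type markers fixed beforehand. It needed at least 3 markers at 20 CPM or more and at least 2-fold above a reference, with 20 CPM added on both sides. The reference was the other clusters for CD45-positive cells and all CD45-positive cells for the macrophage sorts. A cluster stayed unnamed where another class's markers outnumbered its own among the top 10 genes, where a second class had a mean log2 fold over 1.25 and over 0.6 of its own, where no marker led and the lead was under 1, or where cells were shallow with no marker leading. These score thresholds were set after the clusters had been seen. They left 1 macrophage cluster unnamed that lay nearest to interstitial macrophages, with 5.24% of recruited and 9.16% of resident cells at day 3, and a CD45-positive cluster nearest to erythroid cells, with 8.78% of cells at day 3. All unnamed clusters together held 13.1% of recruited and 15.4% of resident cells at day 3, up to 30.5% of a library, and 14.2% of CD45-positive cells. UMIs of the clusters named classical monocyte-like, nonclassical monocyte-like and interstitial macrophage-like were summed per library into 20 profiles of 13249511 to 61189478 UMIs, which the text calls lineage cells. Classical monocyte-like cells of the CD45-positive libraries were summed likewise, to 400970 to 7290831 UMIs.

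Summed counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr and the quasi-likelihood test in 1 fit of 6 group means, with 13853 genes, 14 residual degrees of freedom and a biological coefficient of variation of 0.343. The CD45-positive classical monocyte-like fit had 8712 genes, 6 degrees of freedom and a coefficient of 0.200. Calls are at a Benjamini-Hochberg adjusted p under 0.05, and because the labels do not say that replicates are separate animals, p-values measure only the spread between these libraries, which may be technical. The text gives log2 fold changes ± standard error and group levels as mean CPM ± SD. CD45-positive alveolar macrophage-like cells were not tested because a library held 26 of them, under the 30 cells required. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 23 lists within a comparison, again with a correlation estimated per list, and with fry. The 12 lists on biology and quality were resident perivascular macrophage genes, antigen presentation by MHC class II, monocyte genes, inflammatory cytokines and chemokines, interferon-stimulated genes, proliferation, repair and matrix remodelling, lipid handling and lysosome, apoptotic-cell uptake and complement, glycolysis and hypoxia, oxidative phosphorylation, and dissociation and immediate-early stress. The 11 lists of other cells were neutrophil, alveolar macrophage, T cell, B cell, NK cell, dendritic cell, basophil and mast cell, lung epithelial, endothelial, fibroblast and mural, and erythroid markers.

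Cycling cells were lineage cells with at least 3 UMIs from the proliferation list after each cell was thinned to 2000 UMIs, with shallower cells left out. The sort difference was tested by an exact permutation of sort labels within each day, and the days by exact permutation within each sort. Shares of CD45-positive classes were compared over the 3 days by an exact permutation test, adjusted over 16 classes.

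Sample groups, tests, alternatives, gene lists and cell type markers were chosen before the data were examined, as was the rule for naming genes. For each pair of groups the rule takes the 8 largest rises and the 8 largest falls among called genes with a mean of at least 20 CPM in the higher group and CPM ranges that do not overlap. It takes the 5 largest each way in CD45-positive cells and the 6 largest each way for an interaction, both without the condition on ranges. It adds up to 4 called members of each biology or quality list with the smallest adjusted p, or, where none was called, the member with the highest CPM, and the sort genes in every library. Some genes that the rule takes are not reported here. Immunoglobulin, receptor, haemoglobin, mitochondrial and unnamed genes and members of the contaminant lists were left out of the ranks. A fold against a group at 0 counts is given as a lower bound against a floor of 3 counts over the group, which covers counting error only. Positions are 1-based, from the GENCODE vM21 annotation of GRCm38 (mm10), which held all 115 named genes, 2 of them under another name.

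The tests were run on simulated counts drawn from the real means and library sizes with 200 genes changed, 100 of them at fold 2 and 100 at fold 4. Changed genes had a mean of at least 20 CPM. Counts were drawn independently for each gene, without deviations shared by the genes of a library, so recovery in the real data may be lower. Unchanged genes called numbered 3 to 10 by edgeR and 23 to 40 by DESeq2 in the macrophage comparisons. At day 3 the sort comparison recovered 56% of the genes at fold 2 and 91% at fold 4. For the interaction at day 3 these were 11% and 75%, and for CD45-positive classical monocyte-like cells at day 3 60% and 99%. Recovery at fold 4 was 91% and 86% in the sort comparisons at days 0 and 6, 94% and 92% in resident cells at days 3 and 6, 93% and 88% in recruited cells, 64% for the interaction at day 6 and 99% in CD45-positive cells at day 6.

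Alternatives changed 1 choice at a time: DESeq2 1.42.0, RLE size factors, no low-count filter, all cells, interstitial macrophage-like cells alone, a stricter filter of 500 genes and 5% mitochondrial UMIs, doublets kept, summed counts thinned to the shallowest library, a fit of the compared groups alone, a replicate block and each library left out. Cycling cells were also counted at 1000 and 4000 UMIs and with 2 and 5 UMIs as the minimum, and class shares were tested at Leiden resolutions 0.5 and 2 and on a log2 scale with 0.1 percentage points added. Chosen after the data had been seen were a term for the software version, the version 3.1.0 libraries alone, barcodes found in 2 or more libraries removed, class shares among named leukocytes, cycling in interstitial macrophage-like cells alone, the tests of cycling at each day and of the difference in its rise, and the day 0 libraries resident 1 and recruited 3 left out, which were picked because their profiles stood apart.

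Replicate numbers were checked as pairs by correlating deviations from group means over 5846 genes. All 3 same-numbered pairs exceeded a correlation of 0.1 between sorts at day 6 (0.488, 0.723 and 0.818), between days 0 and 6 in resident cells (0.360, 0.400 and 0.618) and between days 0 and 6 in recruited cells (0.406, 0.182 and 0.584), so blocked values are given there where they change a call. In each other comparison at least 1 pair did not, down to -0.084 between sorts, -0.188 between days 0 and 3 and -0.177 in CD45-positive cells. This criterion was applied per comparison after the blocked counts could be seen. Cells were handled with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.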

Results

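The study asked how 2 populations of mouse lung interstitial macrophages, those already labelled with tdTomato before injury (resident) and those without the label (recruited), respond to lipopolysaccharide given into the airways. Single-cell RNA was counted in 29 libraries: 9 of all CD45-positive lung cells, 10 of resident and 10 of recruited macrophages, taken at day 0 (no lipopolysaccharide), day 3 and day 6. Groups had n = 3 libraries, or n = 4 for the macrophage sorts at day 3. Total UMIs per library ran from 20016865 in resident day 0 replicate 3 to 75250576 in recruited day 3 replicate 2. Expression is given as CPM of counts summed over the lineage cells of each library.

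The genes behind the sort were present in each of the 20 macrophage libraries. Ptprc, which encodes CD45, lay between 434 and 1599 CPM. Fcgr1, which encodes CD64, lay between 68.4 and 382 CPM. C5ar1, which encodes CD88, lay between 30.9 and 418 CPM. Cx3cr1, the chemokine receptor whose promoter drives the label, lay between 123 and 399 CPM. Clusters named monocyte-like or interstitial macrophage-like held 68.3 ± 13.2% (SD), 72.0 ± 5.24% and 75.1 ± 9.64% of recruited cells at days 0, 3 and 6. They held 70.4 ± 2.24%, 61.7 ± 11.1% and 74.6 ± 6.34% of resident cells. At day 0 interstitial macrophage-like cells made up 14.5 ± 22.2% of the recruited sort, with 1.21% to 40.1% in single libraries. They made up 49.3 ± 27.1% of the resident sort. The recruited and resident shares were 54.3 ± 7.44% and 53.0 ± 15.3% at day 3 and 34.4 ± 13.2% and 65.4 ± 6.39% at day 6. Classical monocyte-like cells were 23.8 ± 21.0%, 8.09 ± 1.43% and 16.3 ± 4.94% of the recruited sort. In the resident sort they were 1.70 ± 2.19%, 0.568 ± 0.610% and 0.594 ± 0.515%. These shares were not tested, because the genes that name the clusters also differed between groups. The clusters that held the largest part of the interstitial macrophage-like cells differed between the sorts at days 0 and 3. In recruited cells they were cluster 26 at day 0 (36.0% of that class), clusters 2 and 24 at day 3 (44.7% and 41.5%) and cluster 6 at day 6 (47.0%). In resident cells they were cluster 5 (43.6%), cluster 7 (29.5%) and cluster 6 (39.8%). Cluster 26 was about as common in resident cells at day 0, with 37.0% of that class. Cells were pooled over libraries for these shares, and 1077 of the 1165 recruited cells of that class at day 0 came from replicate 3.

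**Figure D1:**
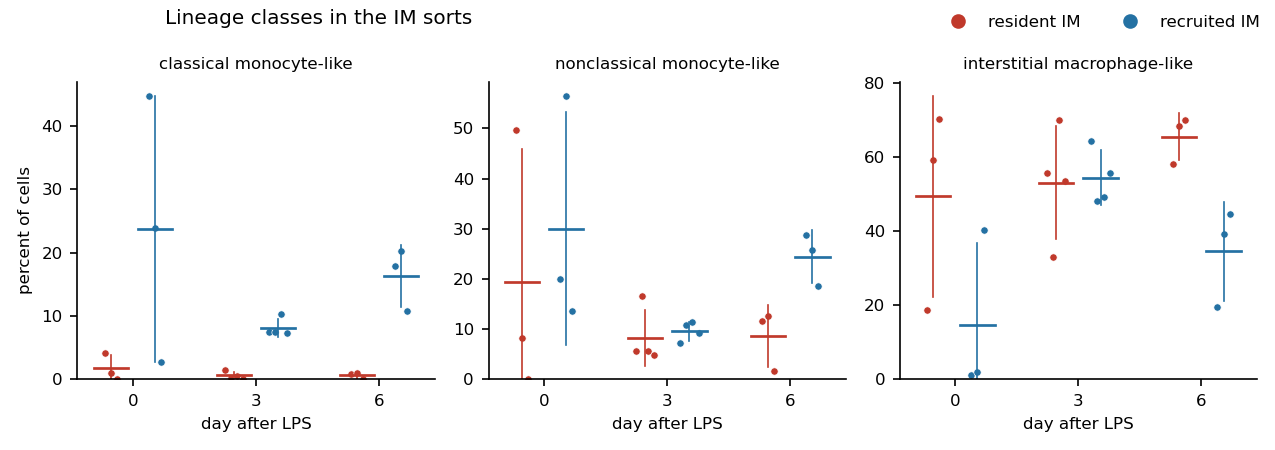
Share of cells (percent, y axis) in the classical monocyte-like, nonclassical monocyte-like and interstitial macrophage-like classes of the recruited and resident sorts at days 0, 3 and 6 (x axis); points are libraries, lines are means and bars are SD, drawn from 0 where the SD exceeds the mean. At day 0 the interstitial macrophage-like share of the recruited libraries runs from 1.21% to 40.1%, and at day 3 the group means are 54.3% and 53.0%.

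Among all CD45-positive cells, alveolar macrophage-like cells, the phagocytes of the airspace, made up 18.7 ± 8.11% at day 0, 1.39 ± 1.07% at day 3 and 10.1 ± 12.2% at day 6 (SD, n = 3 libraries a day). Neutrophil-like cells made up 2.74 ± 2.52%, 18.3 ± 13.8% and 5.08 ± 4.65%. Mature dendritic cell-like cells, which carry antigen to lymph nodes, made up 0.323 ± 0.265%, 1.12 ± 0.263% and 0.605 ± 0.125%. T cell-like cells were 8.13 ± 5.93%, 20.1 ± 3.34% and 15.0 ± 6.61%. Endothelial cell-like cells, which the CD45 gate should exclude, were 24.4 ± 11.6%, 4.27 ± 3.11% and 8.63 ± 4.18%. Several of these means moved by over 1.5 times without 1 library. At day 6 alveolar macrophage-like cells averaged 3.20% without replicate 1 and neutrophil-like cells 2.40% without replicate 2. At day 3 alveolar macrophage-like cells averaged 0.768% and endothelial cell-like cells 2.62% without replicate 1. At day 0 neutrophil-like cells averaged 1.41% without replicate 1, T cell-like cells 4.79% without replicate 2 and mature dendritic cell-like cells 0.174% without replicate 3. None of the 16 classes passed the exact permutation test over the 3 days after adjustment. Swapping whole days leaves the statistic of this test unchanged, so after adjustment over 16 classes a single class alone could not pass. The failure is therefore no evidence that the shares stayed the same. Mature dendritic cell-like cells came nearest (exact p = 0.00714 over 1680 assignments, adjusted p = 0.114), followed by endothelial cell-like cells (exact p = 0.0464, adjusted p = 0.329). Day 3 against day 0 alone cannot go below an exact p of 0.1 with 3 libraries a day.

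**Figure D2:**
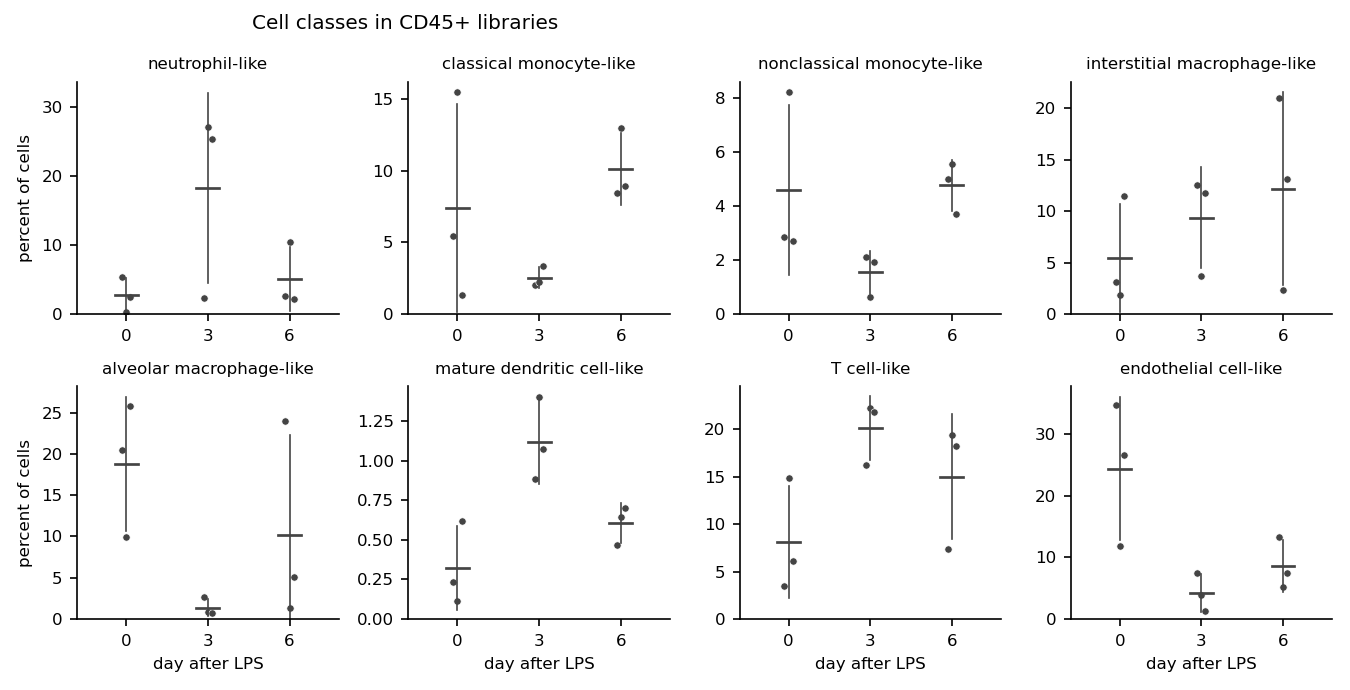
Share of CD45-positive cells (percent, y axis) in 8 cell classes at days 0, 3 and 6 after lipopolysaccharide (x axis); points are libraries (n = 3 a day), lines are means and bars are SD. Alveolar macrophage-like cells average 18.7% at day 0 and 1.39% at day 3, and neutrophil-like cells 2.74% and 18.3%, with no class past the adjusted threshold. A single class alone could not pass that threshold.

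Before lipopolysaccharide, 2 genes were called between recruited and resident lineage cells in the fit without a replicate block. Fn1, which encodes the matrix protein fibronectin (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), was higher in recruited cells by a log2 difference of 3.66 ± 0.52 (adjusted p = 0.0239). It stood at 474 ± 233 against 37.6 ± 21.9 CPM. Klhl38, the other call, named after its values were seen, had 0 counts in recruited against 28 in resident cells (adjusted p = 0.0431). Its level in resident cells was 0.172 to 0.940 CPM. The 15 monocyte genes had a median log2 difference of 2.13, 1 of them called higher and 8 when adjusted over the list alone (camera adjusted p = 1.26e-12, adjusted p = 0.369 with an estimated correlation). The 21 interferon-stimulated genes had a median of 1.64, with 0 called and 17 higher when adjusted over the list alone (camera adjusted p = 1.95e-12, adjusted p = 0.369 with an estimated correlation). The 18 resident perivascular macrophage genes had a median of -1.88, with 0 called and 1 lower when adjusted over the list alone (camera adjusted p = 8.70e-09, adjusted p = 0.369 with an estimated correlation). Markers of the monocyte and resident lists also name the clusters, so their directions are tied to the makeup of each sort.

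Other lists past camera at day 0 were MHC class II genes (median -0.83, adjusted p = 0.00288, adjusted p = 0.526 with an estimated correlation) and apoptotic-cell uptake genes (-0.92, adjusted p = 0.00930, adjusted p = 0.502 with an estimated correlation). Glycolysis genes had a median of 0.38 (adjusted p = 0.00208, adjusted p = 0.502 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.22 (adjusted p = 0.0241, estimated-correlation adjusted p = 0.817) and proliferation genes -0.34 (adjusted p = 0.00288, estimated-correlation adjusted p = 0.639). Cd74, the MHC class II chaperone, stood at 5834 against 14989 CPM without passing the test (log2 difference -1.36 ± 0.57, adjusted p = 0.243). Among markers of other cells, erythroid genes had a median of 2.55 (adjusted p = 0.00288, adjusted p = 0.369 with an estimated correlation). They summed to 269 CPM in recruited against 50.02 in resident cells. Neutrophil markers had a median of 0.84 (adjusted p = 0.000322, estimated-correlation adjusted p = 0.369). Fibroblast and mural markers had a median of -0.996 (adjusted p = 0.00208, estimated-correlation adjusted p = 0.502). Lung epithelial markers also lay lower by camera (mean -0.97, adjusted p = 0.0143, estimated-correlation adjusted p = 0.597), although their sum was 1038 against 682 CPM. Inflammatory cytokines (median -0.46, mean -0.17, tested direction up, adjusted p = 0.934), repair genes (0.37, adjusted p = 0.854), lipid handling genes (-0.28, adjusted p = 0.122) and immediate-early stress genes (-0.21, adjusted p = 0.577) did not pass. Neither did alveolar macrophage (adjusted p = 0.469), T cell (0.0597), B cell (0.141), NK cell (0.780), dendritic cell (0.640), basophil and mast cell (0.934) or endothelial markers (0.486).

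The day 0 sort comparison called 2 genes in total (edgeR, unadjusted p under 0.05 for 2411, DESeq2 551). Without recruited replicates 1, 2 and 3 it called 0, 0 and 2237. Without resident replicates 1, 2 and 3 it called 2528, 0 and 0, with Fn1 and Klhl38 both lost wherever the count was 0 (highest adjusted p 0.206 for Fn1 and 0.217 for Klhl38). The difference of Fn1 was 4.26 without resident replicate 1. Fn1 also lost its call with all cells summed, under the stricter cell filter and in a fit of the compared groups alone. Libraries of software version 3.1.0 alone called 309, and 5062 were called without resident replicate 1 and recruited replicate 3, left out because they stood apart. With the replicate number as a block the day 0 comparison called 2389. Same-numbered day 0 libraries correlated at 0.503, 0.062 and 0.697 between sorts, so whether the numbers pair them stays open.

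At day 3, 96 genes were called higher and 534 lower in recruited than in resident cells. Ccr2, the receptor that brings monocytes out of the marrow (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), was higher in recruited cells by a log2 difference of 1.63 ± 0.33 (adjusted p = 0.00861). It stood at 709 ± 78.7 against 229 ± 39.4 CPM. Fn1 was higher by 1.95 ± 0.42 (adjusted p = 0.0127). Vcan, which encodes the matrix proteoglycan versican (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509), was higher by 3.1 ± 0.71 (adjusted p = 0.0187). Cxcl13, a chemokine that attracts B cells (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), was lower in recruited cells by a log2 difference of -7.87 ± 1.5 (adjusted p = 0.00664). It stood at 2.91 ± 2.46 against 678 ± 433 CPM. Nes, which encodes the intermediate filament nestin (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451), was lower too (-5.25 ± 0.90, adjusted p = 0.00365). So was Kitl, which encodes stem cell factor (ENSMUSG00000019966, chromosome 10, 100015630 to 100100416; -4.26 ± 0.87, adjusted p = 0.0103). The lipid scavenger receptor gene Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) was lower at 34.4 ± 15.1 against 182 ± 42.4 CPM (-2.40 ± 0.37, adjusted p = 0.00237). Fcgrt, which encodes the neonatal Fc receptor (ENSMUSG00000003420, chromosome 7, 45092990 to 45103851), was at 72.1 ± 11.1 against 224 ± 40.5 CPM (-1.64 ± 0.28, adjusted p = 0.00365).

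By list at day 3, 5 of 15 monocyte genes were called higher in recruited cells and 12 when adjusted over the list alone (median 2.12, camera adjusted p = 9.80e-08, adjusted p = 0.480 with an estimated correlation). Of 18 resident perivascular macrophage genes 2 were called lower and 10 when adjusted over the list alone (median -2.64, camera adjusted p = 9.80e-06, adjusted p = 0.583 with an estimated correlation). Cbr2 and Fcgrt were the 2. Of interferon-stimulated genes 1 was called higher, Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960; 24.1 ± 10.6 against 4.58 ± 2.92 CPM, log2 difference 2.39 ± 0.50, adjusted p = 0.0110). Adjusted over the list alone 9 were (median 1.01, camera adjusted p = 2.96e-07, estimated-correlation adjusted p = 0.480). Proliferation genes had a median of -0.94 with 1 called lower, the replication helicase gene Mcm6 (-1.17 ± 0.30, adjusted p = 0.0325). Adjusted over the list alone 1 was (camera adjusted p = 9.51e-08, estimated-correlation adjusted p = 0.490). Glycolysis genes had a median of 0.70 with 0 called and 8 higher when adjusted over the list alone (camera adjusted p = 1.21e-05, estimated-correlation adjusted p = 0.480). Oxidative phosphorylation genes had a median of 0.41 (camera adjusted p = 0.000205, estimated-correlation adjusted p = 0.806). Neutrophil markers moved with these, summing to 644 CPM in recruited against 279 in resident cells (median 1.06, camera adjusted p = 2.24e-05, estimated-correlation adjusted p = 0.480). MHC class II genes did not pass (median 0.19, adjusted p = 0.478), with Cd74 at a log2 difference of -0.01 ± 0.49. Apoptotic-cell uptake genes had 3 called lower (median -0.42, adjusted p = 0.135), among them the scavenger receptor gene Marco at 1.88 against 42.4 CPM (-4.48 ± 1.00, adjusted p = 0.0162).

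The count of 630 genes at day 3 was 318, 362, 327 and 278 without recruited replicates 1 to 4. It was 408, 300 and 369 without resident replicates 2 to 4 and 605 in libraries of version 3.1.0. With the replicate number as a block it was 2854, with same-numbered libraries correlated at 0.881, 0.679, 0.425 and -0.084 between sorts. Of 27 called genes that the naming rule took here, 8 held without each of the 8 libraries. They included Ccr2, Cxcl13, Nes, Kitl, Cd36, Fcgrt and Ifi44. The calls of Kitl and Marco were lost when all cells were summed. The difference of Cxcl13 was -8.62 without recruited replicate 1. The stricter cell filter ended the calls of Fn1, Vcan and Mcm6. That of Fn1 was lost without recruited replicate 3, that of Vcan without recruited replicate 3 or resident replicates 2, 3 or 4. That of Marco was lost without recruited replicates 1, 3 or 4, and those of Mcm6 and Cbr2 were lost without 7 of the 8.

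**Figure D3:**
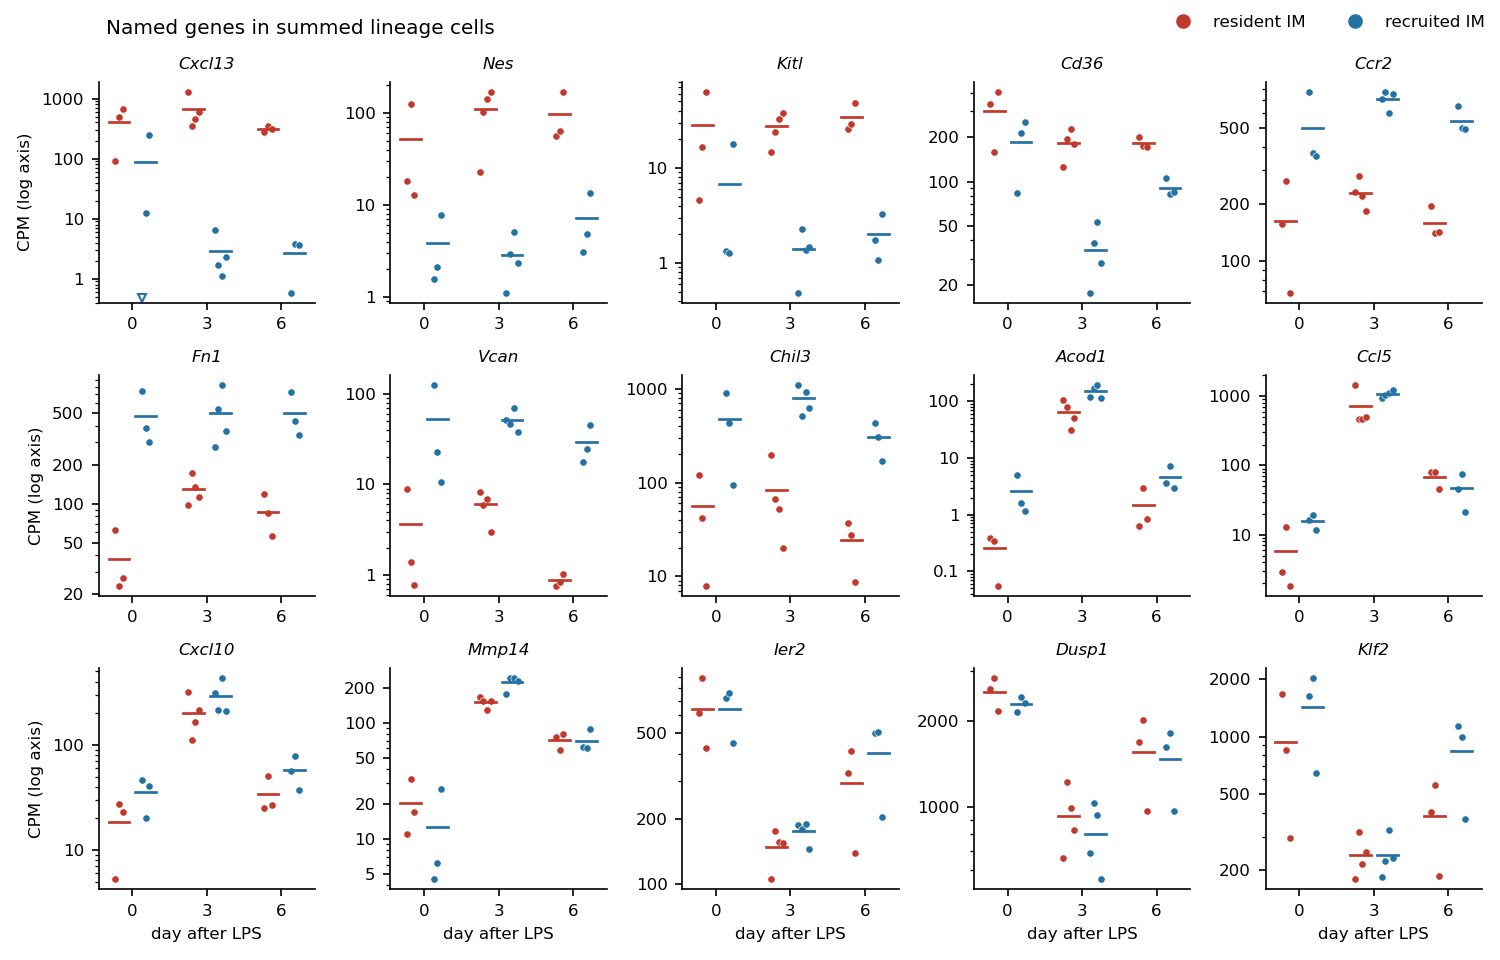
Expression of 15 genes named in the text (CPM of summed lineage cells, log y axis) in recruited and resident libraries at days 0, 3 and 6 (x axis); points are libraries, lines are means and an open triangle at the foot of the axis marks the library at 0. At day 3 Cxcl13 averages 2.91 CPM in recruited and 678 CPM in resident cells, and Ccl5 averages 728 CPM in resident cells at day 3 against 5.82 CPM at day 0.

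At day 6, 5 of 15 monocyte genes were called higher in recruited cells and 12 when adjusted over the list alone (median 2.99, camera adjusted p = 1.67e-11, adjusted p = 0.598 with an estimated correlation). Vcan was higher by a log2 difference of 5.04 ± 0.95 (adjusted p = 0.0220), Fn1 by 2.53 ± 0.49 (adjusted p = 0.0236) and Ccr2 by 1.79 ± 0.38 (adjusted p = 0.0318). Resident cells had more Adam33, which encodes a membrane metalloprotease (ENSMUSG00000027318, chromosome 2, 131050591 to 131063814). It was at 24.7 ± 3.55 against 0.645 ± 0.192 CPM (-5.21 ± 0.86, adjusted p = 0.0149). They also had more Cyr61, which encodes a secreted matrix-associated protein (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981; -5.54 ± 1.06, adjusted p = 0.0220). Cxcl13 was at 316 ± 38.9 CPM in resident against 2.66 ± 1.80 CPM in recruited cells (-6.86 ± 1.67, adjusted p = 0.0461). Of 18 resident perivascular macrophage genes 1 was called lower, Fcgrt (-1.41 ± 0.32, adjusted p = 0.0379). There were 11 when adjusted over the list alone (median -2.79, camera adjusted p = 1.74e-06, estimated-correlation adjusted p = 0.598). Interferon-stimulated genes had 0 called and 10 higher when adjusted over the list alone (median 1.38, camera adjusted p = 2.14e-07, estimated-correlation adjusted p = 0.598). Glycolysis genes had a median of 0.68 (camera adjusted p = 0.000818, estimated-correlation adjusted p = 0.598) and proliferation genes 0.83 (camera adjusted p = 0.00109, estimated-correlation adjusted p = 0.830). Fibroblast and mural markers were at 232 against 369 CPM (median -1.39, camera adjusted p = 0.00490, estimated-correlation adjusted p = 0.697). Neutrophil markers were at 257 against 147 CPM (0.88, camera adjusted p = 0.00201, estimated-correlation adjusted p = 0.598).

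This comparison called 242 genes at day 6, 53 higher and 189 lower in recruited cells. With the replicate number as a block it called 2760, which added Apoe (-0.83, adjusted p = 0.0422), Gapdh (0.66, adjusted p = 0.0124) and Ifi27l2a (0.72, adjusted p = 0.0450) to the named calls. Without recruited replicates 1, 2 and 3 the count was 0, 0 and 1. Without resident replicates 1, 2 and 3 it was 33, 20 and 34. No named call held without each library, Adam33 being lost only without a recruited library and Cyr61 without those or resident replicate 2 (-6.78 without recruited replicate 1). In interstitial macrophage-like cells alone Vcan and Fn1 lost their calls, and under the stricter cell filter Cxcl13 and Fcgrt lost theirs. Version 3.1.0 libraries called 61, and sums over all cells 0 (edgeR, unadjusted p under 0.05 for 1689; DESeq2 1007 in lineage cells).

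In resident cells, 7 of 26 inflammatory and 7 of 21 interferon-stimulated genes rose by day 3. Both lists lost their camera call with an estimated correlation (adjusted p = 0.271 and adjusted p = 0.212). Acod1, which makes itaconate in activated macrophages (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), rose from 0.263 ± 0.181 to 66.3 ± 32.0 CPM (log2 change 7.91 ± 0.81, adjusted p = 0.000142). Ccl5, a chemokine for T cells and monocytes (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), rose from 5.82 ± 6.03 to 728 ± 492 CPM (6.96 ± 0.75, adjusted p = 0.000203). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), had 0 counts at day 0 and 927 at day 3. It was at least 145-fold higher against a floor of 3 counts over the group (adjusted p = 0.00140). The interleukin 1 antagonist gene Il1rn rose by 2.41 ± 0.31 (adjusted p = 0.00116). The membrane collagenase gene Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364) rose by 2.89 ± 0.50 (adjusted p = 0.00580). Immediate-early genes were among the falls. The transcription factor gene Ier2 (ENSMUSG00000053560, chromosome 8, 84661331 to 84662852) went from 644 ± 235 to 149 ± 30.3 CPM (-2.12 ± 0.36, adjusted p = 0.00562). The phosphatase gene Dusp1 (ENSMUSG00000024190, chromosome 17, 26505590 to 26562128) went from 2527 ± 332 to 927 ± 238 CPM (-1.45 ± 0.28, adjusted p = 0.0135).

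By list, 2 of 28 proliferation genes rose over all genes, the mitotic kinase gene Bub1 (2.68 ± 0.65, adjusted p = 0.0392) and the kinesin gene Cenpe (2.47 ± 0.63, adjusted p = 0.0473). Adjusted over the list alone 21 rose (median 1.79, camera adjusted p = 2.23e-16, adjusted p = 0.212 with an estimated correlation). Of 21 interferon-stimulated genes 7 rose and 10 when adjusted over the list alone (median 1.16, camera adjusted p = 2.44e-11, estimated-correlation adjusted p = 0.212). The GTPase gene Gbp2 rose by 3.83 ± 0.55. Of 26 inflammatory genes 7 rose, and 10 rose and 2 fell when adjusted over the list alone (median 0.70, camera adjusted p = 0.000100, estimated-correlation adjusted p = 0.271). Of 18 repair genes 5 rose, and 6 rose and 1 fell when adjusted over the list alone (median 0.62, camera adjusted p = 0.000234, estimated-correlation adjusted p = 0.212). Of 18 stress genes 5 fell and 9 when adjusted over the list alone (median -1.04, camera adjusted p = 6.93e-09, estimated-correlation adjusted p = 0.210). Lipid handling (0.31, camera adjusted p = 0.000248, estimated-correlation adjusted p = 0.212), oxidative phosphorylation (0.32, camera adjusted p = 0.00119, estimated-correlation adjusted p = 0.626) and glycolysis genes (0.39, camera adjusted p = 0.00354, estimated-correlation adjusted p = 0.471) had smaller medians. Markers of other cells moved too. Lower were endothelial (-1.37, camera adjusted p = 3.92e-05, estimated-correlation adjusted p = 0.212), erythroid (-5.30, camera adjusted p = 0.00354, estimated-correlation adjusted p = 0.337) and lung epithelial markers (-0.83, camera adjusted p = 0.00354, estimated-correlation adjusted p = 0.471). Neutrophil markers were higher (0.88, camera adjusted p = 0.00590, estimated-correlation adjusted p = 0.471).

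Between days 0 and 3 resident cells gave 325 calls, 196 higher and 129 lower. A fit of the compared groups alone gave 20, 18 higher and 2 lower, and ended the calls of Dusp1 and Gbp2. The count was 206 and 835 without day 0 replicates 1 and 2, and 155, 190 and 191 without day 3 replicates 1, 3 and 4. It was 25 in version 3.1.0 libraries, where Acod1, Ccl5 and Il1rn kept their calls and Nos2, Mmp14, Ier2 and Dusp1 did not. The change of Ccl5 was 8.25 without day 0 replicate 2. Of 31 called genes that the naming rule took here, 19 held without each of the 7 libraries. The calls of the 7 genes named first in resident cells held without each of the 7 libraries, while those of Bub1 and Cenpe were lost without 6.

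By day 6 a single gene was called in resident cells. Inhba, which encodes a subunit of the secreted factor activin A (ENSMUSG00000041324, chromosome 13, 16011851 to 16031621), rose from 0.0924 ± 0.0805 to 7.54 ± 1.3 CPM (log2 change 6.22 ± 0.74, adjusted p = 0.00217). It was named after its values were seen. Cd74 (0.72, adjusted p = 0.897), Apoe, which carries lipid out of macrophages (0.93 ± 0.49, adjusted p = 0.855), and the transcription factor gene Klf2 (-1.29 ± 0.56, adjusted p = 0.854) did not pass. Camera placed lipid handling (median 0.33, adjusted p = 2.94e-05, adjusted p = 0.330 with an estimated correlation), MHC class II (0.52, adjusted p = 0.000530, estimated-correlation adjusted p = 0.628) and repair genes (0.29, adjusted p = 0.000580, estimated-correlation adjusted p = 0.480) above other genes. There were 3 repair genes higher when adjusted over the list alone. Proliferation (-0.46, adjusted p = 0.000229, estimated-correlation adjusted p = 0.628) and stress genes (-0.42, adjusted p = 0.00123, estimated-correlation adjusted p = 0.579) lay below. So did endothelial (-1.17, adjusted p = 3.56e-06, estimated-correlation adjusted p = 0.330) and lung epithelial markers (-0.74, adjusted p = 0.000338, estimated-correlation adjusted p = 0.628). Fibroblast and mural markers lay above (0.59, adjusted p = 0.0459, estimated-correlation adjusted p = 0.707). Monocyte genes did not pass (-1.71, adjusted p = 0.156; 0.0239 with the replicate block). Inhba held without each of the 6 libraries (adjusted p 0.00586 to 0.0441). No gene was called with all cells summed (edgeR, unadjusted p under 0.05 for 813), in interstitial macrophage-like cells alone (620) or in a fit of the compared groups alone (274). The count of calls was 44 without day 0 replicate 2, and version 3.1.0 libraries called 0 (edgeR, unadjusted p under 0.05 for 545; DESeq2 20 in all libraries).

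In recruited cells, 8 of 26 inflammatory and 7 of 18 repair genes rose by day 3, and 1 of each list fell. Both lists lost their camera call with an estimated correlation (adjusted p = 0.297 for each). Interstitial macrophage-like cells went from 14.5% to 54.3% of the recruited sort between these days. Changes in the summed lineage cells may therefore partly follow this makeup. Ccl5 rose from 15.8 ± 3.70 to 1085 ± 124 CPM (log2 change 6.10 ± 0.72, adjusted p = 0.000223). Acod1 rose from 2.61 ± 2.12 to 151 ± 40.5 CPM (5.84 ± 0.69, adjusted p = 0.000223) and Inhba from 0.593 ± 0.393 to 25.9 ± 10.2 CPM (5.44 ± 0.60, adjusted p = 0.000223). Nos2 had 0 counts at day 0 and 3237 at day 3, at least 422-fold higher (adjusted p = 0.000223). Mmp14 rose from 12.6 ± 12.5 to 222 ± 30.5 CPM (4.14 ± 0.53, adjusted p = 0.000346). The lipid receptor gene Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) rose by 1.85 ± 0.35 (adjusted p = 0.00399), and the lysosomal protease gene Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038) by 1.99 ± 0.41 (adjusted p = 0.00754). Falls included Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), a transcription factor that restrains myeloid activation, from 1435 ± 713 to 241 ± 58.1 CPM (-2.57 ± 0.52, adjusted p = 0.00675). The transcription factor gene Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222) fell by 2.61 ± 0.35 (adjusted p = 0.000433). Retnla, which encodes a secreted resistin-like protein (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), fell as well (-5.43 ± 1.27, adjusted p = 0.0139).

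By list, 8 of 26 inflammatory genes rose and 1 fell, against 10 and 2 when adjusted over the list alone (median 0.91, camera adjusted p = 3.57e-05, adjusted p = 0.297 with an estimated correlation). Of 18 repair genes 7 rose and 1 fell, or 8 and 2 when adjusted over the list alone (0.65, camera adjusted p = 0.000167, estimated-correlation adjusted p = 0.297). Of 22 lipid handling genes 5 rose and 1 fell, or 12 and 1 when adjusted over the list alone (0.69, camera adjusted p = 2.61e-05, estimated-correlation adjusted p = 0.297). Cd36 was the one that fell (-2.42 ± 0.39, adjusted p = 0.00163). Of 12 MHC class II genes 1 rose, the protease gene Ctss (0.91 ± 0.19, adjusted p = 0.00777). Adjusted over the list alone 6 rose (1.11, camera adjusted p = 0.000116, estimated-correlation adjusted p = 0.414). Interferon-stimulated genes had 5 rises and 7 when adjusted over the list alone (0.66, camera adjusted p = 0.000116, estimated-correlation adjusted p = 0.451). Proliferation genes had 0 called (1.19, camera adjusted p = 2.00e-07, estimated-correlation adjusted p = 0.414). Oxidative phosphorylation had 2 rises (0.51, camera adjusted p = 0.000175, estimated-correlation adjusted p = 0.547) and glycolysis 2 rises (0.53, camera adjusted p = 0.00156, estimated-correlation adjusted p = 0.451). Of 18 stress genes 7 fell, and 1 rose and 9 fell when adjusted over the list alone (-1.01, camera adjusted p = 0.000167, estimated-correlation adjusted p = 0.297). Endothelial (-2.19, camera adjusted p = 0.000861, estimated-correlation adjusted p = 0.414) and erythroid markers (-8.54, camera adjusted p = 0.000291, estimated-correlation adjusted p = 0.297) were lower. Neutrophil markers were higher (0.45, camera adjusted p = 0.0466, estimated-correlation adjusted p = 0.547). Resident perivascular macrophage genes (-1.64, adjusted p = 0.942) and monocyte genes (-0.56, adjusted p = 0.394) did not pass as lists. Lyve1, a hyaluronan receptor of perivascular macrophages, was called lower (-5.23 ± 1.42, adjusted p = 0.0270) with overlapping ranges.

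Between days 0 and 3 recruited cells gave 1583 calls, 753 higher and 830 lower. The count was 911, 538 and 2402 without day 0 replicates 1, 2 and 3. It was 723 and 700 without day 3 replicates 1 and 4, and 665 in version 3.1.0 libraries. Of 44 called genes that the naming rule took here, 33 held without each of the 7 libraries. Each gene named above for recruited cells at day 3 held its call without each of the 7 libraries except Lyve1, whose change was 0.06 without day 0 replicate 3 and whose call was also lost without day 3 replicates 1, 3 and 4. Without day 0 replicate 3 the change was 5.36 for Mmp14, 2.61 for Ctsd and -3.55 for Retnla. It was 6.77 for Acod1 without day 0 replicate 1, 6.08 for Inhba without day 0 replicate 2, -6.31 for Retnla without day 3 replicate 3 and -5.90 for Lyve1 without day 3 replicate 2. Acod1, Inhba and Trem2 lost their calls in interstitial macrophage-like cells alone, Retnla with all cells summed and Klf2 in version 3.1.0 libraries.

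**Figure D4:**
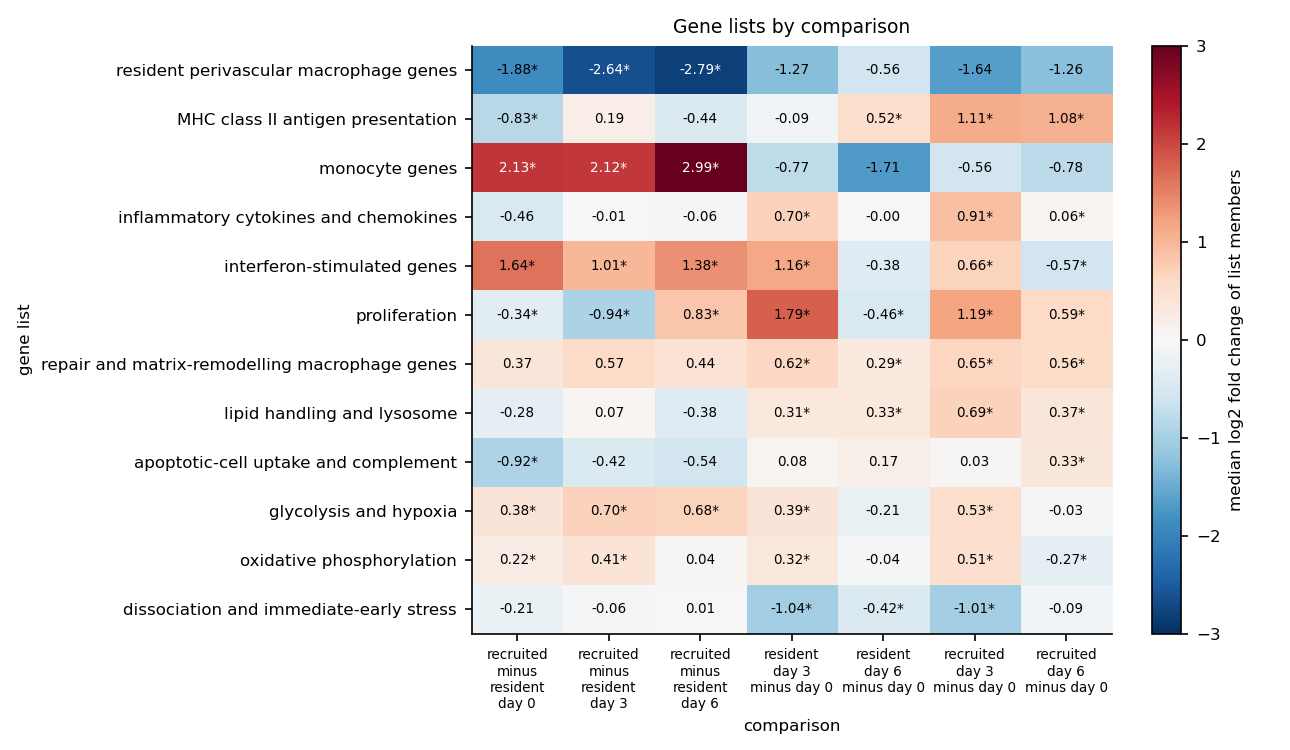
Median log2 change (colour and printed value) of 12 gene lists (rows) in 7 comparisons of lineage cells (columns); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Proliferation genes have a median of 1.79 in resident and 1.19 in recruited cells at day 3, and no list passes with an estimated correlation.

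By day 6 no gene was called in recruited cells (edgeR 0, unadjusted p under 0.05 for 859, DESeq2 50). Interstitial macrophage-like cells alone gave 94 calls, 32 higher and 62 lower, with 35 and 53 cells in day 0 replicates 1 and 2. Without resident replicate 1 and recruited replicate 3 of day 0, left out because they stood apart, there were 929, of which 829 were higher. Apoe averaged 13868 CPM at day 6 against 5048 at day 0 (log2 change 1.46 ± 0.50, adjusted p = 0.609), and Cd74 16669 against 5834 CPM (1.51 ± 0.57, adjusted p = 0.685). MHC class II genes had a median of 1.08 (camera adjusted p = 8.09e-09, adjusted p = 0.215 with an estimated correlation). Repair genes had a median of 0.56 with 4 higher when adjusted over the list alone (camera adjusted p = 1.08e-06, estimated-correlation adjusted p = 0.111) and lipid handling genes 0.37 with 6 higher when adjusted over the list alone (camera adjusted p = 2.97e-06, estimated-correlation adjusted p = 0.111). Proliferation genes had a median of 0.59 (camera adjusted p = 2.54e-07, estimated-correlation adjusted p = 0.443) and apoptotic-cell uptake genes 0.33 (camera adjusted p = 0.00481, estimated-correlation adjusted p = 0.443). Interferon-stimulated genes had a median of -0.57 (camera adjusted p = 0.000640, estimated-correlation adjusted p = 0.598) and oxidative phosphorylation genes -0.27 (camera adjusted p = 0.00374, estimated-correlation adjusted p = 0.612). Inflammatory genes passed with a median of 0.06 (camera adjusted p = 0.0294, estimated-correlation adjusted p = 0.598), but not with the replicate block (adjusted p = 0.0967). Markers of other cells past camera were erythroid (-6.40, adjusted p = 1.31e-07, estimated-correlation adjusted p = 0.111), endothelial (-1.03, adjusted p = 0.000351, estimated-correlation adjusted p = 0.349) and neutrophil (-0.88, adjusted p = 0.0138, estimated-correlation adjusted p = 0.598). So were lung epithelial (-0.58, adjusted p = 0.0257, estimated-correlation adjusted p = 0.612) and fibroblast and mural (0.50, adjusted p = 0.0118, estimated-correlation adjusted p = 0.598). Without day 0 replicate 3 the count was 430, without day 6 replicate 3 it was 1, and version 3.1.0 libraries called 0 (unadjusted p under 0.05 for 819).

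Whether the sorts responded differently was tested as an interaction of sort and day. No gene was called at day 3 (edgeR 0, unadjusted p under 0.05 for 366, DESeq2 0) or day 6 (edgeR 0, unadjusted p under 0.05 for 98, DESeq2 0). In interstitial macrophage-like cells alone 63 genes were called at day 3, 62 of them lower, and 1 at day 6, with sums of 35 and 53 cells in recruited day 0 replicates 1 and 2. Without resident replicate 1 and recruited replicate 3 of day 0, both left out after the data had been seen, the counts were 1127 and 378, and most went the other way (791 and 364 higher). At day 3 MHC class II genes changed more in recruited cells by camera (median 1.07, adjusted p = 1.71e-06, adjusted p = 0.782 with an estimated correlation) and interferon-stimulated genes less (-0.74, adjusted p = 0.000241, estimated-correlation adjusted p = 0.802). Cd74 was at 1.36 ± 0.75 and Apoe at 1.70 ± 0.65 (adjusted p = 1.00 for both). At day 6 proliferation genes had a median of 1.06 (camera adjusted p = 1.07e-25, adjusted p = 0.123 with an estimated correlation). Without recruited day 0 replicate 3 the counts were 111 at day 3 (109 higher) and 29 at day 6 (29 higher), and without resident day 0 replicate 1 it was 1 at day 3. Version 3.1.0 libraries called 0 at both (unadjusted p under 0.05 for 988 and 175).

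Cycling cells, those with at least 3 UMIs from the proliferation list, made up 3.17 ± 1.33%, 14.4 ± 3.43% and 2.70 ± 1.43% of resident lineage cells at days 0, 3 and 6 (SD). In recruited cells the shares were 2.22 ± 1.82%, 5.56 ± 0.679% and 3.25 ± 1.26%. Resident cells had more over the 3 days, by 3.07 percentage points (two-sided exact permutation within days, p = 0.0126 over 28000 assignments). With the replicate number as a block this difference did not pass (exact permutation p = 0.0527), nor did the changes over the days in either sort (exact permutation p = 0.0833 for both). The blocked test over the days left out replicate 4. Where days 0 and 6 are alike, exchanging them within a replicate hardly changes its statistic, so it can miss a clear day 3 rise. The share changed over the days in resident cells (exact permutation p = 0.00333, 4200 assignments) and in recruited cells (exact permutation p = 0.0300). By day, tested after the data had been seen, the difference was 8.80 points at day 3 (exact p = 0.0286, the smallest possible, adjusted p = 0.0857) against 0.947 at day 0 (exact p = 0.5) and -0.544 at day 6 (exact p = 0.8). Within interstitial macrophage-like cells the day 3 shares were 16.6 ± 3.5% and 7.07 ± 0.532%. Over the 3 days their difference was -2.37 points (exact p = 0.751) and the recruited change -9.70 (exact p = 0.433). Recruited day 0 libraries ranged there from 5.49% to 37.1%, with 35 and 53 such cells in 2 of them. Nonclassical monocyte-like cells, used as background, gave 3.13 ± 1.29% in resident and 0.918 ± 0.430% in recruited libraries at day 3. Their median depths were 5601 and 8052.5 UMIs against 17613 and 18334.25 in lineage cells. Thinning left out 121, 211 and 91 resident and 86, 236 and 101 recruited cells. Unthinned shares were 37.5%, 62.7% and 47.0% against 29.1%, 54.5% and 33.8%, and the ranges of the sorts then overlapped at day 3. The recruited change was lost without day 0 replicate 1 or 2 (exact p = 0.0690 for both), day 3 replicate 1 (exact p = 0.0607), day 3 replicates 2, 3 or 4 (exact p = 0.0536 each) or day 6 replicate 3 (exact p = 0.0508). It was also lost in version 3.1.0 libraries (exact p = 0.152), where the resident change (exact p = 0.00952) and the sort difference (3.33 points, exact p = 0.0417) passed.

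**Figure D5:**
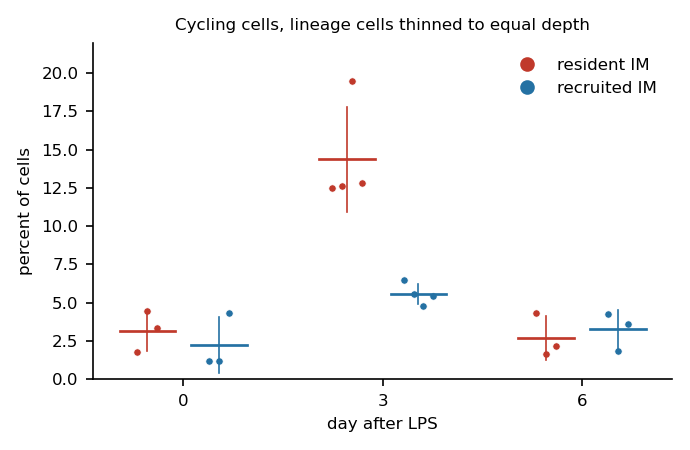
Share of lineage cells (percent, y axis) with at least 3 UMIs from the proliferation list after thinning to 2000 UMIs, in resident and recruited libraries at days 0, 3 and 6 (x axis); points are libraries, lines are means and bars are SD. At day 3 resident libraries average 14.4% and recruited libraries 5.56%.

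In classical monocyte-like cells of the CD45-positive libraries, 7 genes were higher and 4 lower at day 3. Chil3, a chitinase-like protein of activated myeloid cells (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), rose from 868 ± 335 to 2838 ± 264 CPM (log2 change 1.71 ± 0.26, adjusted p = 0.0153). AA467197, whose product is a mitochondrial protein induced in inflammation (ENSMUSG00000033213, chromosome 2, 122636986 to 122641191), rose by 3.81 ± 0.63 (adjusted p = 0.0260). The membrane protein gene Tmem176a (ENSMUSG00000023367, chromosome 6, 48840919 to 48847071) fell from 223 ± 21.3 to 72.7 ± 11.2 CPM (-1.61 ± 0.20, adjusted p = 0.00537). The interferon-induced gene Ifi27l2a fell from 2155 ± 442 to 647 ± 105 CPM (-1.74 ± 0.23, adjusted p = 0.00813). By day 6 no gene was called (edgeR 0, unadjusted p under 0.05 for 331, DESeq2 0). The day 3 count of 11 was 19 and 0 without day 0 replicates 1 and 2, 2 and 1 without day 3 replicates 1 and 3, and 22 in version 3.1.0 libraries. The calls of Chil3, AA467197, Tmem176a and Ifi27l2a were lost without day 0 replicate 2 or day 3 replicate 3, and those of Chil3, AA467197 and Ifi27l2a also without day 3 replicate 1. The change of AA467197 was 4.71 without day 0 replicate 2.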

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

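The tests of the cycling pattern, the difference in its rise between sorts, the test of a single wrong label and the reading of the 2 day 0 libraries' sort scores were chosen after those results had been seen; the tests of immediate-early genes were fixed before theirs.

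Resident replicate 1 and recruited replicate 3 stood apart from the other day 0 libraries, and leaving both out raised the day 0 sort comparison from 2 to 5062 genes. A label exchange needs both out of place. In interstitial macrophage-like cells resident replicate 1 lay on the resident side of the sort score's midpoint (-1.089 in log2, day 6 SD 0.236). This argues against an exchange, but exchanged labels called 5251 genes, so it stays open. The criterion set beforehand asked for both on their own side. Recruited replicate 3 lay at -0.524, on the resident side within the recruited SD of 0.683, so the reading was changed after this was seen. Against a single wrong label of recruited replicate 3, 1.45% of its cells were basophil or mast cell-like (exact 95% binomial interval 1.03% to 1.98%). A resident day 0 library had at most 0.103% (0.0213% to 0.301%). Single genes went both ways. Ccr2 (356 CPM), Fn1 (298 CPM, called under these labels), Vcan (10.7 CPM) and Nes (7.80 CPM) lay outside the resident range on the recruited side. Cxcl13 (249 CPM), Kitl (17.7 CPM) and Chil3 (94.3 CPM) lay within it. For Cxcl13 and Chil3 that rested on resident replicate 1 (90.9 and 120 CPM), the other library that stood apart. Resident replicates 2 and 3 had 485 and 659 CPM of Cxcl13 and 41.7 and 7.91 CPM of Chil3. A mixture of the sorts was not tested. Across genes resident replicate 1's deviation correlated with the nonclassical monocyte-like minus interstitial macrophage-like difference (r = 0.895; -0.725 for recruited replicate 3; genes are not independent replicates). Its class shares, whose origin stays open, imply this, so it tests no cause. Shared barcodes do not explain them: its nonclassical monocyte-like share was 49.8% without.

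Resident cells had a larger day 3 rise in cycling cells than recruited cells, by 7.86 percentage points (exact permutation p = 0.0329 over 1400 assignments). The permutation exchanged sort labels within day 0 and within day 3. It therefore assumes no sort difference on either day, which is more than equal rises, and it ignores replicate numbers. Against more monocyte-like cells in the recruited sort as the whole cause, the day 3 difference within interstitial macrophage-like cells was 9.53 points. Free RNA from cycling cells would raise other cells too. Nonclassical monocyte-like cells differed by 2.21 points at day 3 (3.13% in resident against 0.918% in recruited libraries, with ranges that do not overlap). A share above a fixed UMI minimum need not rise by equal points in cells with different baselines, so this test cannot decide on free RNA. Without barcodes found in 2 or more libraries the day 3 difference in lineage cells was 8.10 points. A biological difference between the sorts may remain as a hypothesis found and tested on the same data, and the recruited day 0 shares within interstitial macrophage-like cells, from 5.49% to 37.1%, leave the size of the rise there open.

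Immediate-early genes were lower at day 3 than at day 0 in both sorts, with list medians of -1.04 in resident and -1.01 in recruited lineage cells. Most of these genes were not called in either sort. The list lost its camera call with an estimated correlation (adjusted p = 0.210 in resident and 0.297 in recruited cells). In endothelial cell-like cells of the same libraries the median was -0.576 in the resident and -0.709 in the recruited sort, against -1.097 and -1.185 in the matched lineage sums, so handling of the tissue that differed between days may contribute. Against a shift in monocyte-like shares as the whole cause, the medians within interstitial macrophage-like cells were -1.294 and -1.348. A response of both cell types to lipopolysaccharide stays open and was not tested.

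Single libraries lay far from the other 3 of their day 3 group in 14 of 161 groups of 4, where chance gives 5%; each is given with the gap divided by the range, against the critical value for 4 samples. In resident cells Ccl5 stood at 1465 CPM in replicate 1 against 469 to 506 (0.963), Gapdh at 1266 CPM in replicate 1 against 841 to 875 (0.921) and Thbd at 23.7 CPM in replicate 2 against 9.35 to 11.5 (0.848). Cycling cells were 19.5% in resident replicate 3 against 12.5% to 12.8% (0.952), and nonclassical monocyte-like cells 16.5% in replicate 2 against 4.80% to 5.67% (0.926). NK cell-like cells were 6.93% in resident replicate 1 against 0.353% to 0.561% (0.968), and fibroblast or mural cell-like cells 13.3% in replicate 2 against 1.5% to 1.77% (0.977). In recruited cells H2-M2 stood at 8.91 CPM in replicate 2 against 3.92 to 4.11 (0.962), Spon1 at 39.2 CPM in replicate 1 against 20.5 to 22.5 (0.893) and Wfdc21 at 86.1 CPM in replicate 1 against 35.5 to 43.1 (0.849). Classical monocyte-like cells were 10.2% in recruited replicate 3 against 7.29% to 7.47% (0.938), and in replicate 2 NK cell-like cells were 0.408% against 0.187% to 0.198% (0.953), T cell-like cells 1.98% against 1.22% to 1.31% (0.880) and fibroblast or mural cell-like cells 5.68% against 0.922% to 1.54% (0.869).

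By camera, 8 lists differed between the sorts in their change by day 3, and each lost its call with an estimated correlation. These were MHC class II genes (median 1.07, adjusted p = 1.71e-06, adjusted p = 0.782 with an estimated correlation), interferon-stimulated genes (-0.74, adjusted p = 0.000241, estimated-correlation adjusted p = 0.802), monocyte genes (-0.30, adjusted p = 0.00119, estimated-correlation adjusted p = 0.802) and lipid handling genes (0.31, adjusted p = 0.0350, estimated-correlation adjusted p = 0.802). Among markers of other cells they were fibroblast and mural (0.34, adjusted p = 0.00747, estimated-correlation adjusted p = 0.802), lung epithelial (0.58, adjusted p = 0.0213, estimated-correlation adjusted p = 0.8286), T cell (0.37, adjusted p = 0.0224, estimated-correlation adjusted p = 0.311) and erythroid markers (-3.16, adjusted p = 0.0272, estimated-correlation adjusted p = 0.802). By day 6 there were 5: proliferation (1.06, adjusted p = 1.07e-25, estimated-correlation adjusted p = 0.123), erythroid markers (-4.56, adjusted p = 3.45e-08, estimated-correlation adjusted p = 0.123), interferon-stimulated genes (-0.34, adjusted p = 0.00443, estimated-correlation adjusted p = 0.876), MHC class II genes (0.51, adjusted p = 0.0156, estimated-correlation adjusted p = 0.876) and oxidative phosphorylation (-0.25, adjusted p = 0.0191, estimated-correlation adjusted p = 0.910).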

How the results depend on the processing

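Chosen after the data had been seen were the software version term, the version 3.1.0 libraries alone, the removal of shared barcodes, the 2 day 0 libraries left out and cycling in interstitial macrophage-like cells alone. Counts below are genes called, and where they differ from the counts in the text by more than 1.5 times the cause was not tested. With 3 or 4 libraries a group, a fit without 1 of them assumes that the rest vary like the other groups.

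DESeq2 called 551, 1218 and 1007 genes between sorts at days 0, 3 and 6, 930 and 20 in resident and 2427 and 50 in recruited cells at days 3 and 6, and 41 in CD45-positive classical monocyte-like cells at day 3. Sums over all cells called 1, 240 and 0 between sorts and 216 and 0 in resident cells at days 3 and 6. With interstitial macrophage-like cells alone the counts were 21, 1438 and 434 between sorts, 562 and 0 in resident cells, 94 in recruited cells at day 6, and 63 and 1 for the interactions at days 3 and 6. The stricter cell filter gave 0, 262 and 58 between sorts, 188 and 2 in resident cells and 4 in recruited cells at day 6. Thinning to the shallowest library gave 4 between sorts at day 0, 5 in recruited cells at day 6 and 7 in CD45-positive cells at day 3. A fit of the compared groups alone gave 0, 2237 and 1561 between sorts and 20 and 0 in resident cells. Without a low-count filter recruited cells at day 6 gave 5, and CD45-positive cells 273 and 111 at days 3 and 6.

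The replicate block gave 2389, 2854 and 2760 genes between sorts, 499 in resident cells at day 3 and 1 for the interaction at day 3. Libraries correlated best with their own number in 16 of 20 between sorts, 23 of 36 between days and 7 of 18 in CD45-positive cells. Between days they cannot share a mouse. In the 3 comparisons with all pairs over 0.1 the block changed no other named or list call than those in the text. A software version term gave 68, 1046 and 723 between sorts, 507 in resident cells at day 3, 5 in recruited cells at day 6 and 18 in CD45-positive cells at day 3. Version 3.1.0 libraries alone gave 309 and 61 between sorts at days 0 and 6, 25 and 0 in resident cells, 665 in recruited cells at day 3 and 22 in CD45-positive cells at day 3. Without resident replicate 1 and recruited replicate 3 of day 0 the counts were 5062, 1882 and 2211 between sorts, 504 in resident cells at day 3, 3478 and 929 in recruited cells, and 1127 and 378 for the interactions; the recruited day 3 change of Lyve1 then turned to 0.078 (adjusted p = 0.967) and the interaction of Pf4 at day 3 to 4.5 (adjusted p = 0.0378). The change of Stmn1 in recruited cells at day 3 turned to -1.53 in interstitial macrophage-like cells alone (adjusted p = 0.0445).

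Without 1 library at a time the counts ran from 0 to 2528, 278 to 702 and 0 to 34 between sorts at days 0, 3 and 6, 155 to 835 and 1 to 44 in resident cells, 538 to 2402 and 0 to 430 in recruited cells, 0 to 111 and 0 to 29 for the interactions, and 0 to 19 and 0 to 0 in CD45-positive cells at days 3 and 6. The number of CD45-positive classes past the test was 0 to 0, though a single class alone could not pass it. The recruited day 3 change of Lyve1 ran from -5.9 to 0.055, the latter without recruited day 0 replicate 3.

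The cycling difference ran from 2.50 to 3.42 points, its resident change from 9.48 to 11.8 and its recruited change from 2.81 to 4.39. With the replicate block the exact permutation p was 0.0527 for the difference of 3.07 over 1024 assignments, and 0.0833 for the changes of 11.2 and 3.34. In interstitial macrophage-like cells alone the difference was -2.37 (exact p = 0.751) and the recruited change -9.70 (exact p = 0.433). The recruited change lost its call at 4000 UMIs (3.66, exact p = 0.211), with at least 2 UMIs (3.35, exact p = 0.164), in all cells (2.50, exact p = 0.219) and in version 3.1.0 libraries (2.51, exact p = 0.152).

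The 84 list calls over the 9 comparisons became 0 with an estimated correlation. By fry, which tests whether a list's genes move one way on balance, 7 lists passed in resident and 8 in recruited cells at day 3, 3 in recruited cells at day 6 and 0 in the other 6 comparisons. With all cells summed, adjusted p-values of lists whose direction turned were 0.471 and 0.137 for fibroblast and mural markers between sorts at days 0 and 6, 0.0674 for their interaction at day 3, 0.000696 for NK cell markers between sorts at day 3, 2.54e-06 for the T cell marker interaction at day 3 and 0.0411 for T cell markers in resident cells at day 3. Called named genes kept their call in 1540 cases under the other settings, lost it in 215 and turned in 1. Without single libraries 582 were kept, 320 lost and 1 turned. Class shares kept their side in 153 cases under other settings and 153 without single libraries, with a smallest adjusted p of 0.0571 to 0.560. No single class could pass this adjusted test alone. Tests of CD45-positive alveolar macrophage-like cells were not run. At these depths the recovery of changes of fold 2 was 8% to 66% in simulated genes of at least 20 CPM. Small changes that were not called are therefore not shown to be absent.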

Other observations

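The splits of the libraries below were fixed before their results were seen, whereas barcodes shared between libraries were counted only after the data had been seen.

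Among further genes called in resident cells at day 3, Saa3, an acute-phase apolipoprotein, rose from 5.37 to 424 CPM (log2 change 6.32 ± 1.46, adjusted p = 0.0308), and Arg1, the arginase of repair macrophages, from 0.512 to 27.8 CPM (5.79 ± 1.3, adjusted p = 0.0252). The interferon-induced chemokine genes Cxcl9 (4.67 ± 0.94, adjusted p = 0.0142) and Cxcl10 (3.44 ± 0.55, adjusted p = 0.00422) and the GTPase gene Iigp1 (4.77 ± 0.77, adjusted p = 0.00436) rose too. Thbd, which encodes the anticoagulant thrombomodulin, fell by 2.24 ± 0.42 (adjusted p = 0.0106). Without resident day 0 replicate 1 the calls of Saa3, Arg1 and Cxcl9 were lost, and Saa3 also without day 3 replicates 1 and 4. Without day 0 replicate 3 the change was 9.23 for Saa3, 6.51 for Arg1 and 6.06 for Iigp1, and without day 3 replicate 1 it was 3.88 for Cxcl9.

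In recruited cells at day 3 the cytokine gene Il1a (3.86, adjusted p = 0.00110), the stem cell antigen gene Ly6a (4.80) and the lysosomal gene Ctsl (1.76, adjusted p = 0.00440) rose, as did Tgfbi, a matrix protein induced by TGF-beta (1.52 ± 0.28, adjusted p = 0.00380). The glycolytic gene Tpi1 (1.21, adjusted p = 0.0122) and the hypoxia gene Bnip3 (1.53, adjusted p = 0.00401) rose with them, and each of these calls held without each of the 7 libraries, with Il1a at 4.61 without day 0 replicate 3. Recruited cells also had more Chil3 than resident cells at day 3, at 794 ± 271 against 83.7 ± 77.4 CPM (3.25 ± 0.83, adjusted p = 0.0319), a call lost without each library but resident replicate 1, without which it was 4.10.

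Markers of other cells summed to at most 1038 CPM per group, in lung epithelial markers of recruited cells at day 0, against 682 in resident cells. Alveolar macrophage markers summed to 165, 159 and 146 CPM in recruited cells at days 0, 3 and 6 and to 84.1, 85.2 and 61.6 CPM in resident cells. Day 3 replicate 1 of the recruited and resident sorts shared 306 barcodes, against 32 in the next pair of libraries and a median of 3.

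Other splits of the same libraries were counted for each comparison. At day 3, 1 of 35 splits, the real one, gave as many genes as called between sorts (630, highest other 0), in resident cells (325, highest other 46) and in recruited cells (1583, highest other 0). Each is at the smallest share that 35 splits allow, with no adjustment for the 3 comparisons, so chance is not excluded. The resident count was 20 in a fit of the compared groups alone and 25 in version 3.1.0 libraries. With 10 splits of 3 against 3 a share under 0.05 cannot be had. Between sorts at day 0, 3 of 10 gave as many (2). The highest other, 5251, exchanged the 2 day 0 libraries, which points to a structure of the samples or an exchange. As many were given by 1 of 10 between sorts at day 6 (242, highest other 0, and 0 also among the 3 splits that part as many pairs), 1 of 10 in resident cells at day 6 (1, highest other 0), 10 of 10 in recruited cells at day 6 (0, highest other 5), and 1 and 10 of 10 in CD45-positive classical monocyte-like cells at days 3 and 6 (11 and 0, highest other 1 and 0). For the interactions the real split called 0 genes, so all 100 of 100 splits gave as many by construction, as did the 10 of 10 above, and these counts say nothing of chance. The highest gave 4730 at day 3 and 5049 at day 6, which points to a structure of the samples, and 1832 and 800 among splits that did not exchange the 2 day 0 libraries.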
